A study of Homo sapiens with 20 samples.

How the data were processed

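RNA was measured by sequencing in 20 samples whose source is given as SW1990, an established human pancreatic cancer cell line. Per the labels, total RNA was extracted with TRIzol, ribosomal RNA was removed, and libraries were made with a directional (strand-keeping) kit. The submitters' processing notes name the aligner HISAT2, the assembler StringTie and the human genome build hg38, with no versions. The gene annotation, any filter, the strand setting and any step to set aside mouse reads are not given in the sources used here. The deposited table holds counts, as whole numbers per gene and sample that the authors had not normalised, and its totals differ between samples. It has 60656 rows with 59609 distinct gene symbols, of which 12589 rows have no count in any library and 1047 rows repeat the symbol of an earlier row. Positions came from GENCODE release 29 on the same build, where 56501 of the distinct symbols matched 1 gene.

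Samples were grouped by the treatment in their labels into 4 groups of 5, and the replicate number of a sample is the number in its title. The sources do not state whether replicates are different mice, tumours or cultures, so every p-value measures only the spread between these samples. A letter at the end of each title, b or C, is not explained there and was tried as a covariate. The comparisons were the test of any difference among the 4 treatments, the 6 pairs of treatments, and each treatment against the mean of the other 3. These comparisons, the gene lists, the rule for naming genes and the alternatives not marked otherwise were chosen before the data were examined.

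Counts were normalised by TMM (trimmed mean of M-values) and tested with edgeR 4.0.16 in R 4.3.3 with robust quasi-likelihood F-tests, all 20 samples in 1 fit. The default filter of edgeR, with a minimum count of 10, left 24790 rows. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Group values are TMM-normalised CPM (counts per M counts, where M stands for mega), given as mean ± SD over 5 samples, and fold changes are on the log2 scale with their standard error (SE). DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were run as other tools on the same comparisons.

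The 42 gene lists covered pathways, tumour subtypes and markers of other cell types. Those with at least 5 tested members, 41 lists, were tested with camera from limma, which compares the members of a list with all other genes, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The list of red blood cell genes had 2 tested members and was not tested. Adjusted p-values are over the 41 lists within a contrast, and with the calls of each comparison the text gives the adjusted p of the same test with a correlation estimated from the data. The list test fry was run as well. Members of a list were also counted 1 by 1 from the edgeR test, adjusted over all genes and adjusted over the list alone. Exact permutation tests and linear models of list means per library were added after the list results were seen.

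Genes are named in the text by a fixed rule. They have a gene symbol and a mean log2 CPM of 0 or more. For each pair these were the passing genes with the smallest p, up to 6 in each direction, and for each treatment against the rest up to 8. Where none passed, they were the 3 with the smallest unadjusted p in each direction. For the 4-group test they were the 10 with the smallest p, and for each list past its threshold the 4 members with the smallest p in its direction. The text describes a part of these and gives the others as counts of list members. SH2D5, AL355075.4, APOL1 and the structural RNA genes RN7SK, RPPH1 and RMRP, AL136295.5 and STAT6, given for their overlap with a named gene, and the islet genes INS and GCG fall outside the rule and were chosen after their values were seen.

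Total counts per sample were 81.7 to 135 M. Intervals for ratios of counts are exact 95% intervals and cover counting error only, since reads carry no molecular identifiers. Alternatives were the normalisations RLE and upper quartile, no filter and a strict filter (1 CPM in 5 samples), the title letter, the replicate number as a block, the mean level of host marker genes as a covariate, a minimum absolute log2 fold change of 1, each pair fitted alone, and leaving out each library in turn. Chosen after seeing the data were a fit without the 5 libraries with a high RN7SK share, a term for these libraries, and a covariate for each library's slope of expression against GC content. The slope used expression relative to each gene's mean over all libraries. The share of distance between samples that lies between groups was tested by 100000 permutations of the labels. The edgeR test and the list tests were tested on simulated data with known changes before use. False calls were 2.5 to 6% of the edgeR calls in comparisons with changes. Camera with either correlation and fry found 5 of 5 shifted lists and called 0 of 26 others. The genes were simulated independently of one another and without RN7SK-high libraries. The simulation therefore does not show how the tests behave with correlated genes or such libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.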

Results

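Gene expression was measured in 20 samples of SW1990, a human pancreatic cancer line, which the series places in a mouse model of pancreatic cancer. The labels give 4 treatments, each named after a principle of traditional Chinese medicine, with 5 samples each. They are called here heat-clearing (clearing heat and removing dampness), spleen-strengthening (with regulation of qi), yin-nourishing (with elimination of heat) and blood-activating (with removal of stasis). The sources used here name no herbs, dose or duration, and no sample is labelled untreated, so each value compares treatments with one another. The series asks which transcripts differ between such treatments. Total counts, in M (mega), were 90.0 to 135 M per sample in the heat-clearing group, 81.7 to 110.0 M in the spleen-strengthening group, 83.3 to 104.6 M in the yin-nourishing group and 90.4 to 110.5 M in the blood-activating group. Values with ± are the mean and SD of the 5 samples of a group in normalised CPM (counts per M).

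Treatment accounted for 19.92% of the summed squared distance between the 20 expression profiles, against a mean of 15.8% when the labels were permuted (permutation p = 0.00571, one-sided, 100000 permutations). Without the 5 libraries described next the share was 21.75%, against a mean of 21.43% under permuted labels, and no longer passed (permutation p = 0.324). RN7SK, the small nuclear RNA that holds back the elongation factor P-TEFb, took 5.25 to 7.38% of the counts in 5 libraries and 1.57 to 3.02% in the other 15. The 5 were heat-clearing replicates 01 and 02 and blood-activating replicates 01, 08 and 09, and none came from the spleen-strengthening or yin-nourishing groups. They are called the RN7SK-high libraries below. In these libraries mitochondrially encoded mRNA took 10.6 to 15.6% of the counts, against 17.1 to 23.2% in the other 15. In CPM without TMM scaling RPPH1, the RNA of ribonuclease P, stood at 6543 to 8791 CPM against 1748 to 2733 CPM, and RMRP, the RNA of the related ribonuclease MRP, at 861 to 1553 CPM against 1928 to 2794 CPM. Relative to each gene's mean over the 20 libraries, expression rose with transcript GC content in all 5, by 0.24 to 0.34 on the log2 scale per 10% GC. This slope was -0.21 to 0.02 in the other 15. Being relative, the slopes balance out over the 20 libraries by construction, so the 2 ranges are not separate observations. Of the 60 genes followed by name, 20 had the RN7SK-high libraries wholly on the same side of the other libraries within both the heat-clearing and the blood-activating group. Chance gives 2% for genes picked without regard to their values. The 60 were picked mostly by small p between treatments with unequal numbers of these libraries, so 2% is not a fair reference for them. The share over all tested genes is not given. Higher in the RN7SK-high libraries were PCK2, SHMT2, PFKL, PFKP, LIF, NFKB2, NR4A1, HES1, RPL11, RPL37, FAM83A, TMUB2, MT-TY and CD320. Lower in them were RECQL, RRP1B, GLRX2, MT-ATP6, MT-CO2 and MT-ND4. Group means of all these genes given below include the RN7SK-high libraries, which the groups hold in unequal number.

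**Figure D1:**
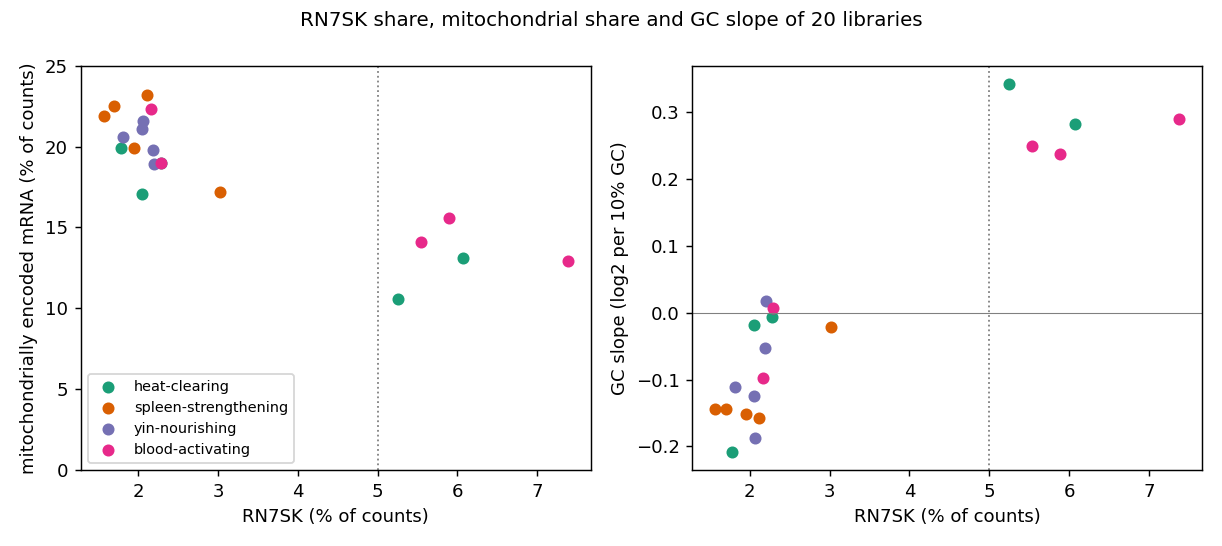
Share of counts from mitochondrially encoded mRNA (left, % of counts) and slope of expression against GC content (right, log2 per 10% GC) against the share of counts from RN7SK (%), 1 point per library, coloured by treatment, with a dotted line at 5%. The 5 libraries right of the line have 10.6 to 15.6% mitochondrial mRNA and slopes of 0.24 or more. Slopes use expression relative to each gene's mean over all libraries.

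The spleen-strengthening group had the lowest levels of NAB2, a corepressor of the early growth response (EGR) transcription factors. Its 5 samples held 5.02 ± 0.626 CPM (SD, n = 5), below each of the other 15 samples, and the groups' means were 9.51 ± 0.995 CPM for heat-clearing, 8.96 ± 1.21 CPM for blood-activating and 7.65 ± 0.659 CPM for yin-nourishing. Against the mean of the other 3 treatments NAB2 fell by 0.79 on the log2 scale (SE 0.127, adjusted p = 0.0354). SH2D5, a gene for an SH2-domain protein, was nearly absent: 4 counts in 452.8 M over the 5 spleen-strengthening samples, all in replicate 02, against 324 counts in 529.5 M in the heat-clearing group. The ratio of the heat-clearing to the spleen-strengthening level was 69.3 (exact 95% interval 26.8 to 256), that for the yin-nourishing group 62.4 (24.1 to 231) and that for the blood-activating group 54.3 (20.9 to 201), and SH2D5 also passed the test (adjusted p = 0.0354). NAB2 lies on chromosome 12 at 57088894 to 57095476 and shares 69 bases with STAT6 on the other strand, and SH2D5 lies on chromosome 1 at 20719732 to 20732837 (hg38).

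In this comparison of spleen-strengthening with the other 3 treatments, edgeR called 2 genes lower and 0 higher among 24790, with 3145 at an unadjusted p under 0.05. DESeq2 called 139 and limma voom 5. Without the RN7SK-high libraries the count was 0 and NAB2 was at -0.75 (adjusted p = 0.323). Over 20 fits that each leave out 1 library the count was 3 without heat-clearing 03 or blood-activating 04, 2 without blood-activating 06, 1 without spleen-strengthening 02 or 05, and 0 in the other 15.

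In the camera test with its preset correlation, 10 of 41 lists of genes fixed in advance passed for the spleen-strengthening group, 9 lower and 1 higher. None of the 10 passed otherwise: adjusted p = 0.959 with an estimated correlation for the hypoxia and acinar lists, adjusted p = 0.72 with an estimated correlation for the other 8, and 0 lists by fry. Genes of the integrated stress response and amino acid supply were lower, 25 of 26 members, with a median log2 fold change of -0.35 (adjusted p = 0.000176). Among them PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, stood at 2.31 ± 0.816 CPM against group means of 2.69 to 4.81 CPM, and SHMT2, which moves 1-carbon units from serine in mitochondria, at 21.4 ± 3.61 CPM against 25.95 to 39.6 CPM. NF-kB and inflammatory genes were lower in 25 of 32 members (median -0.43, adjusted p = 0.00467), among them the cytokine LIF at 61.0 ± 6.16 CPM against 69.4 to 98.9 CPM. Glycolysis genes were lower in 18 of 20 members (median -0.24, adjusted p = 0.00467), among them enolase ENO1 at 312.3 ± 19.3 CPM against 343.9 to 406.8 CPM. Cytosolic ribosomal protein genes were lower in 30 of 40 members (median -0.23, adjusted p = 0.00274). Immediate early genes were lower in 19 of 24 (median -0.21, adjusted p = 0.0245) and hypoxia genes in 21 of 28 (median -0.17, adjusted p = 0.0406). Skin keratinocyte markers were lower in 10 of 13 (median -0.34, adjusted p = 0.0324) and genes of the basal-like tumour subtype in 19 of 25 (median -0.22, adjusted p = 0.0415). The basal-like and keratin genes included FAM83A at 353.1 ± 10.6 CPM against 427.5 to 739.5 CPM and KRT17 at 355.2 ± 52.4 CPM against 415.5 to 714.8 CPM. Pancreatic acinar genes were lower in 19 of 19 (median -3.04, adjusted p = 0.0374), a difference carried by a few libraries of the other groups. The 13 mitochondrially encoded mRNAs were higher, 12 of 13 (median 0.22, adjusted p = 0.00136), with MT-ATP6 at 20950 ± 3875 CPM against 13590 to 19920 CPM.

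No member of these 10 lists passed over all genes, and adjusted over the list alone 4 NF-kB, 2 ribosomal, 2 basal-like, 1 hypoxia and 1 immediate early member were lower. The mitochondrial, basal-like and immediate early calls ended without the RN7SK-high libraries (adjusted p = 0.133, 0.0757 and 0.0699). Leaving out 1 library ended 7 of the 10 calls, and leaving out spleen-strengthening 07 alone ended each of these 7: glycolysis (adjusted p = 0.0521), NF-kB (0.0697), immediate early genes (0.108), keratinocytes (0.22), the basal-like subtype (0.333), acinar genes (0.397) and hypoxia (0.679). Spleen-strengthening 02 did so for NF-kB, the basal-like subtype and keratinocytes (0.0637 to 0.189). The rest ended between 0.0509 and 0.297. Hypoxia ended without heat-clearing 03, yin-nourishing 04 or 10, or blood-activating 06 or 09, and the basal-like subtype without any of these or heat-clearing 09 or spleen-strengthening 06. Immediate early genes ended without yin-nourishing 10, keratinocytes without heat-clearing 09, yin-nourishing 10 or blood-activating 04, and acinar genes without heat-clearing 02 or 03, spleen-strengthening 06 or 08, yin-nourishing 07 or 10, or blood-activating 04 or 06.

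**Figure D2:**
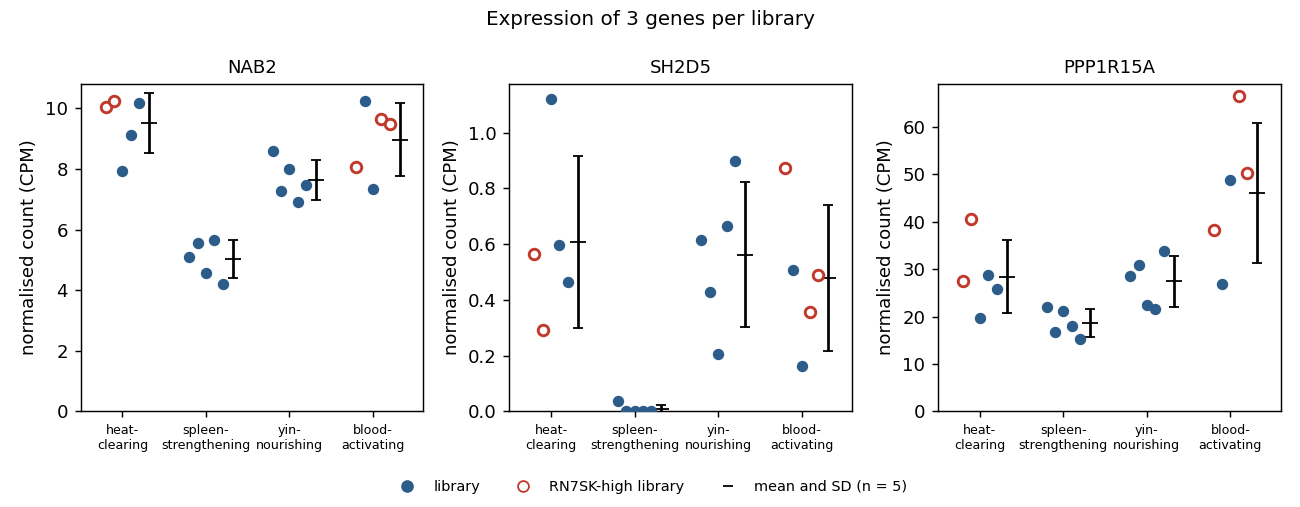
Normalised counts (CPM) of NAB2, SH2D5 and PPP1R15A in each of the 20 libraries by treatment, with open points for RN7SK-high libraries and bars for mean and SD (n = 5). All spleen-strengthening samples lie below every other sample for NAB2 and SH2D5.

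Heat-clearing and spleen-strengthening differed in NAB2 and SH2D5. NAB2 was 9.51 ± 0.995 CPM against 5.02 ± 0.626 CPM (SD, n = 5), a log2 fold change of 0.92 (SE 0.149, adjusted p = 0.0495), and all 5 heat-clearing samples lay above all 5 spleen-strengthening samples. SH2D5 passed at the same adjusted p of 0.0495. The 3 list calls of this pair come from the preset correlation, and each had an adjusted p = 0.925 with an estimated correlation. Integrated stress response genes were higher in the heat-clearing group in 22 of 26 members (median 0.38, adjusted p = 0.00166), with PCK2 at 4.46 ± 0.901 against 2.31 ± 0.816 CPM and the transcription factor CEBPB at 40.3 ± 7.90 against 31.9 ± 3.40 CPM. Glycolysis genes were higher in 19 of 20 members (median 0.27, adjusted p = 0.0049), among them the phosphofructokinase gene PFKL at 38.8 ± 16.1 against 21.7 ± 5.25 CPM and ENO1 at 406.8 ± 70.3 against 312.3 ± 19.3 CPM. Mitochondrially encoded mRNAs were lower in 12 of 13 (median -0.40, adjusted p = 7.07e-07), with MT-ATP6 at 13590 ± 5296 against 20950 ± 3875 CPM. In these lists 0 members passed over all genes or adjusted over the list alone. The heat-clearing group holds 2 RN7SK-high libraries and the spleen-strengthening group 0. edgeR called 2 genes higher and 0 lower, with 2844 at an unadjusted p under 0.05, DESeq2 called 53 higher and 14 lower, and limma voom called 3. The gene count was 0 without the RN7SK-high libraries (NAB2 0.86, adjusted p = 1). Leaving out 1 library at a time it was 2 without heat-clearing 03 or blood-activating 06, 1 without spleen-strengthening 02 or 05, and 0 in the other 16 fits. The glycolysis call ended without heat-clearing 09 (adjusted p = 0.0666).

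Spleen-strengthening and blood-activating were the furthest apart by the count of genes at an unadjusted p under 0.05, yet edgeR called 0 genes in either direction after adjustment. The smallest adjusted p was 0.06, shared by 6 genes, among them PPP1R15A, SH2D5, NAB2, SPRR1A and CDK5R1. PPP1R15A, which directs the phosphatase that ends eIF2alpha-driven translational arrest, was at 18.6 ± 2.89 against 46.1 ± 14.8 CPM (SD, n = 5), a log2 fold change of -1.31 (SE 0.211), and its groups did not overlap. SPRR1A, a cornified envelope protein, was at 2.81 ± 1.19 against 10.5 ± 4.73 CPM. In the other direction CDK5R1, an activator of the kinase CDK5, was at 28.2 ± 3.59 against 16.0 ± 2.39 CPM, the DNA helicase RECQL at 104.7 ± 3.51 against 66.4 ± 10.7 CPM (adjusted p = 0.0835) and the nucleolar protein RRP1B at 43.9 ± 3.91 against 29.6 ± 2.24 CPM (adjusted p = 0.0835).

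In the camera test with its preset correlation 10 of 41 lists passed in this pair, 8 lower and 2 higher in spleen-strengthening. None passed with a correlation from the data: adjusted p = 0.642 with an estimated correlation for the integrated stress response list and adjusted p = 0.915 with an estimated correlation for the other 9. By fry 5 of the 41 lists passed. Over all contrasts only 4 of the 45 camera calls still passed by fry, so not all of these 5 are among the 10. All 26 integrated stress response genes were lower (median -0.59, adjusted p = 2.57e-05), 9 of them adjusted over the list alone. Examples are SHMT2 at 21.4 ± 3.61 against 39.6 ± 16.0 CPM, the amino acid transporter SLC7A5 at 65.9 ± 5.60 against 99.1 ± 16.9 CPM and PCK2 at 2.31 ± 0.816 against 4.81 ± 1.53 CPM. NF-kB and inflammatory genes were lower in 28 of 32 (median -0.61, adjusted p = 0.00537), 7 of them adjusted over the list alone, with LIF at 61.0 ± 6.16 against 98.9 ± 20.8 CPM and NFKB2, an NF-kB subunit, at 8.57 ± 1.15 against 14.0 ± 2.53 CPM. Hypoxia genes were lower in 22 of 28 (median -0.36, adjusted p = 0.0443), 5 of them adjusted over the list alone, led by the angiogenic factor VEGFA at 33.98 ± 5.39 against 68.8 ± 26.5 CPM. Glycolysis genes were lower in 18 of 20 (median -0.34, adjusted p = 0.0222), 8 of them adjusted over the list alone, including the glucose transporter SLC2A1 at 214.1 ± 32.2 against 373.7 ± 134 CPM. Immediate early genes were lower in 21 of 24 (median -0.31, adjusted p = 0.0222), 4 of them adjusted over the list alone, among them the nuclear receptor NR4A1 at 6.79 ± 1.59 against 13.8 ± 3.57 CPM. Wnt and Notch targets were lower in 17 of 23 (median -0.12, adjusted p = 0.04), 4 of them adjusted over the list alone, and these included the Notch target HES1 at 15.2 ± 2.90 against 26.2 ± 4.80 CPM and the receptor NOTCH3 at 66.9 ± 4.49 against 121.2 ± 48.1 CPM. Of these examples SHMT2, PCK2, LIF, NFKB2, NR4A1 and HES1 also separated the RN7SK-high libraries within groups, as given above. SLC7A5, VEGFA, SLC2A1 and NOTCH3 did not do so in both groups.

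Cytosolic ribosomal protein genes moved both ways: 29 of 40 were lower (median -0.29, adjusted p = 0.0222), and adjusted over the list alone 15 were lower and 2 higher, with RPL37 at 35.4 ± 8.23 against 114.0 ± 45.0 CPM. Acinar genes were lower in 19 of 19 (median -3.39, adjusted p = 0.00723). Proliferation genes were higher in 25 of 40 (median 0.16, adjusted p = 0.0447), with the mitotic kinesin KIF20A at 63.5 ± 2.60 against 47.0 ± 8.28 CPM, and mitochondrially encoded mRNAs were higher in 12 of 13 (median 0.29, adjusted p = 0.00537). In these 10 lists 0 members passed over all genes. The blood-activating group holds 3 RN7SK-high libraries and the spleen-strengthening group 0, and without them 7 of the 10 calls ended (adjusted p = 0.0911 to 0.663). The other 3 still passed, with a median of -0.21 for the integrated stress response list (adjusted p = 0.00793), -0.30 for NF-kB (0.0169) and -4.57 for acinar genes (4.44e-07). Of the blood-activating group only 04 and 06 remained in that fit, with acinar sums of 79.25 and 1016 CPM without TMM scaling. Leaving out blood-activating 06 alone ended the acinar call (adjusted p = 0.139). With the host marker score as a covariate the acinar call ended too (median -4.19, adjusted p = 0.271). Without the RN7SK-high libraries the integrated stress response and NF-kB medians were smaller in size than with all libraries (-0.59 and -0.61). With a term for these libraries the mitochondrial list turned to a median of -0.06 (adjusted p = 0.769).

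edgeR counted 5087 genes in this pair at an unadjusted p under 0.05, 3034 of them lower in spleen-strengthening, and DESeq2 called 1933 genes and limma voom 4910. Without the RN7SK-high libraries edgeR called 3 genes. Leaving out blood-activating 04 gave 2002 genes, heat-clearing 03 gave 311, heat-clearing 02 gave 12, heat-clearing 01 and blood-activating 01 gave 2 each and spleen-strengthening 02 gave 1. Blood-activating 04 and heat-clearing 03 are not RN7SK-high, so without them the RN7SK-high libraries made up more of their groups. The calls of 7 lists ended without spleen-strengthening 02, 05 or 07, blood-activating 04, 06, 08 or 09, or heat-clearing 01, 03 or 09 (adjusted p = 0.0504 to 0.671), and those of the integrated stress response, NF-kB and mitochondrial lists in none of the 20 such fits.

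**Figure D3:**
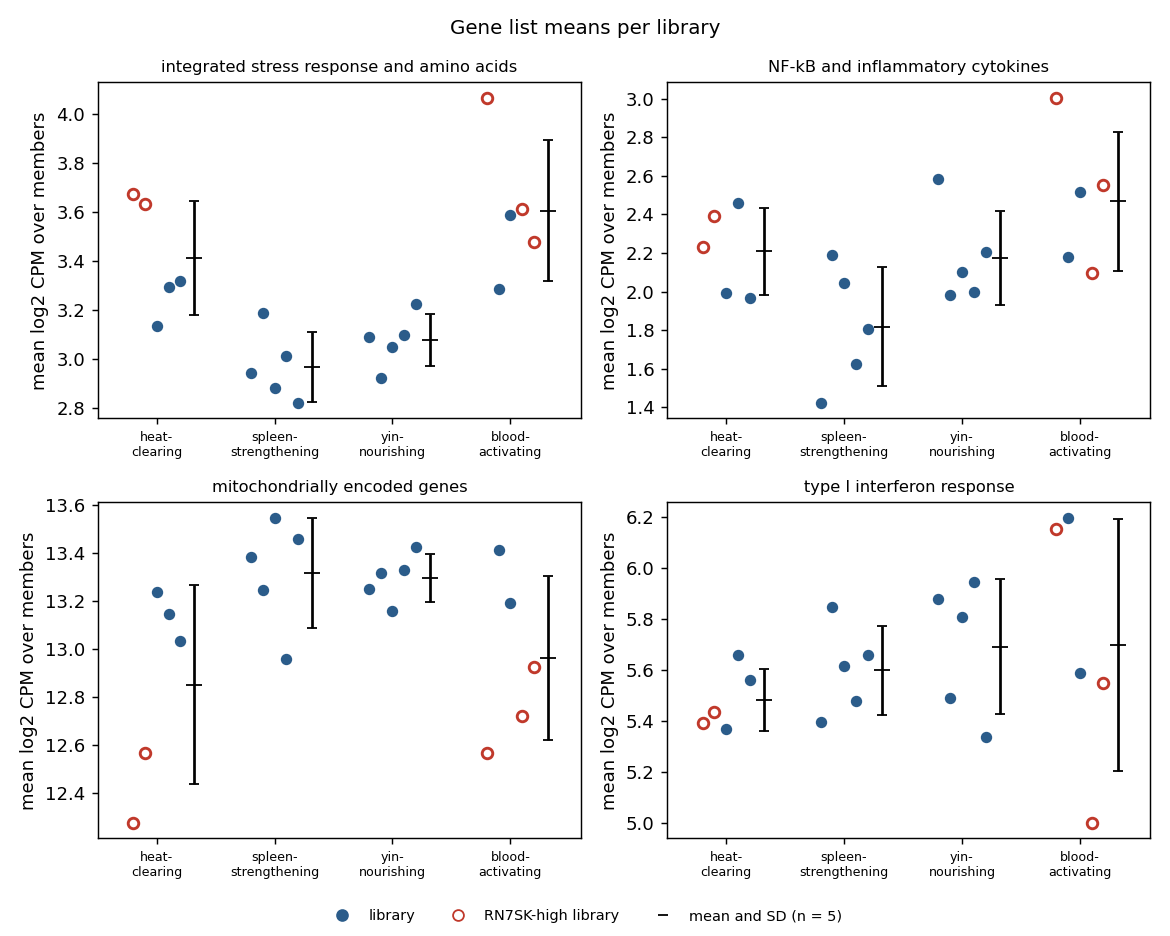
Mean log2 CPM over the members of 4 gene lists in each of the 20 libraries by treatment, with open points for RN7SK-high libraries and bars for mean and SD (n = 5). Every blood-activating library lies above every spleen-strengthening library for the integrated stress response list, and the 5 open points are among the lowest for mitochondrially encoded genes.

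Yin-nourishing and blood-activating differed by 0 genes in edgeR, with a smallest adjusted p of 0.141. GLRX2, a mitochondrial glutaredoxin, was at 37.6 ± 3.20 against 24.1 ± 2.70 CPM (SD, n = 5) and the mitochondrial tRNA gene MT-TY at 38.3 ± 8.64 against 103.8 ± 34.6 CPM, and neither gene's groups overlapped. Both genes also separated the RN7SK-high libraries within groups, as given above: in blood-activating samples MT-TY was at 102.2 to 147.7 CPM in the 3 RN7SK-high libraries and at 63.4 to 77.8 CPM in the other 2. The 3 list calls of this pair had an adjusted p = 0.869 with an estimated correlation. Proliferation genes were higher in yin-nourishing in 26 of 40 members (median 0.21, adjusted p = 0.00269), and adjusted over the list alone 9 were higher and 2 lower. Among them KIF20A was at 74.2 ± 9.16 against 47.0 ± 8.28 CPM and cyclin CCNB2 at 53.4 ± 7.64 against 32.4 ± 7.14 CPM. Integrated stress response genes were lower in 25 of 26 (median -0.46, adjusted p = 0.00269), 5 of them adjusted over the list alone, including CEBPB at 33.6 ± 3.49 against 45.5 ± 8.92 CPM and SLC7A5 at 72.4 ± 7.70 against 99.1 ± 16.9 CPM. Mitochondrially encoded mRNAs were higher in 11 of 13 (median 0.24, adjusted p = 0.0049), with MT-CO2 at 35430 ± 3426 against 22750 ± 9264 CPM. Of the 4512 genes at an unadjusted p under 0.05, 2593 were lower in yin-nourishing, and DESeq2 called 1055 genes and limma voom 4172. The blood-activating group holds 3 RN7SK-high libraries, and without them the integrated stress response (adjusted p = 0.2) and mitochondrial (0.799) calls ended. Leaving out blood-activating 04 gave 361 genes, the proliferation call ended without yin-nourishing 05 (0.139) or blood-activating 08 (0.084), and the mitochondrial call without blood-activating 01 (0.0524).

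Spleen-strengthening and yin-nourishing, the groups with no RN7SK-high library, differed in 4 lists by camera with its preset correlation. None of the 4 passed with an estimated correlation (adjusted p = 0.819 with an estimated correlation for each) or by fry. All 40 cytosolic ribosomal protein genes were lower in spleen-strengthening (median -0.17, adjusted p = 0.000383), with RPL23 at 110.5 ± 7.62 against 136.4 ± 15.8 CPM (SD, n = 5) and RPL11 at 46.2 ± 4.82 against 57.1 ± 6.70 CPM. Nuclear genes of oxidative phosphorylation were lower in 30 of 32 (median -0.11, adjusted p = 0.0168), among them the succinate dehydrogenase subunit SDHB at 29.04 ± 3.11 against 35.5 ± 3.41 CPM. NF-kB and inflammatory genes were lower in 24 of 32 (median -0.21, adjusted p = 0.00546), with IL1B at 17.2 ± 4.42 against 24.8 ± 7.14 CPM, and genes of the basal-like subtype in 19 of 25 (median -0.20, adjusted p = 0.0189), with the cancer-testis antigen LEMD1 at 6.53 ± 2.37 against 9.72 ± 2.19 CPM. In these 4 lists 0 members passed over all genes or adjusted over the list alone. SH2D5 had the smallest p (adjusted p = 0.122). Next among genes with higher counts were GCNT4, a glycosyltransferase of mucin-type sugar chains, at 2.73 ± 0.511 against 5.96 ± 1.81 CPM, and the tight junction protein MARVELD3 at 7.44 ± 2.46 against 3.75 ± 0.675 CPM, and neither passed. edgeR called 0 genes with 1169 at an unadjusted p under 0.05, DESeq2 called 33 and limma voom 1. Leaving out spleen-strengthening 02 gave 1 gene and ended the calls of oxidative phosphorylation (adjusted p = 0.12), the basal-like subtype (0.0593) and NF-kB (0.0593). Leaving out spleen-strengthening 07 ended the same 3 (0.0528, 0.141 and 0.0543). The basal-like call also ended without yin-nourishing 04 (0.0817) or 10 (0.0531).

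Heat-clearing and yin-nourishing differed in the mitochondrially encoded and the interferon lists by camera with its preset correlation, and both had an adjusted p = 0.957 with an estimated correlation. Mitochondrially encoded mRNAs were lower in heat-clearing in 12 of 13 (median -0.39, adjusted p = 7.07e-07), with MT-CO2 at 22770 ± 9819 against 35430 ± 3426 CPM (SD, n = 5). Type I interferon response genes were lower in 30 of 38 (median -0.27, adjusted p = 0.0014), with IFIT5, an interferon-induced RNA-binding protein, at 43.5 ± 8.10 against 59.7 ± 11.6 CPM. In both lists 0 members passed over all genes or adjusted over the list alone. IRF9, a subunit of the interferon-activated factor ISGF3, had a small p as well (0.0025) but shares its span with another annotated gene, to which its counts move in some libraries. Among single genes TMUB2 was at 14.4 ± 2.31 against 8.69 ± 1.23 CPM, the extracellular superoxide dismutase SOD3 at 10.4 ± 0.984 against 15.9 ± 2.85 CPM and the transcriptional corepressor TGIF1 at 21.8 ± 1.90 against 28.9 ± 2.23 CPM, each with an adjusted p = 0.456. edgeR called 0 genes with 2547 at an unadjusted p under 0.05, DESeq2 called 32 and limma voom 0. The heat-clearing group holds 2 RN7SK-high libraries and the yin-nourishing group 0.

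Heat-clearing and blood-activating, the groups that share the RN7SK-high libraries, were the closest pair by the count of genes at an unadjusted p under 0.05, which was 460. Their 5 list calls had an adjusted p = 0.957 with an estimated correlation. Type I interferon genes were lower in heat-clearing in 35 of 38 (median -0.27, adjusted p = 0.000744), with the antiviral synthetase OAS2 at 147.0 ± 12.8 against 197.1 ± 75.9 CPM (SD, n = 5) and TRIM22 at 23.8 ± 6.08 against 36.3 ± 18.5 CPM. NF-kB and inflammatory genes were lower in 27 of 32 (median -0.28, adjusted p = 0.00185), with IL1B at 18.4 ± 4.75 against 29.1 ± 6.25 CPM and CXCL8 at 24.5 ± 5.85 against 39.4 ± 14.0 CPM. Integrated stress response genes were lower in 25 of 26 (median -0.15, adjusted p = 0.0109) and acinar genes in 19 of 19 (median -1, adjusted p = 0.000114). Proliferation genes were higher in 33 of 40 (median 0.10, adjusted p = 0.00493), with the replicative helicase subunit MCM6 at 42.6 ± 5.23 against 35.4 ± 4.76 CPM and the licensing factor CDC6 at 65.3 ± 3.14 against 54.5 ± 9.85 CPM. In the 5 lists 0 members passed over all genes or adjusted over the list alone. Apart from AL355075.4, the single genes with the smallest p were the cytochrome P450 gene CYP2S1 at 4.91 ± 0.901 against 9.51 ± 3.56 CPM and, in the other direction, the mismatch repair gene MSH6 at 76.7 ± 8.96 against 54.2 ± 5.46 CPM (adjusted p = 1 for both). edgeR called 0 genes, DESeq2 called 9 and limma voom 0. The proliferation (adjusted p = 0.236), NF-kB (0.236) and integrated stress response (0.377) calls ended without the RN7SK-high libraries. Single libraries ended each of the 5. These were heat-clearing 01 for proliferation, interferon, NF-kB and acinar genes (0.0532 to 0.19) and heat-clearing 03 for the integrated stress response (0.139). They were blood-activating 01 for interferon, NF-kB and the integrated stress response (0.0632 to 0.266), blood-activating 04 for interferon (0.538), blood-activating 06 for acinar genes (0.109) and blood-activating 08 for proliferation (0.948).

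Blood-activating against the other 3 treatments gave higher stress and inflammatory genes by camera with its preset correlation. The 4 list calls had an adjusted p = 0.879 with an estimated correlation. All 26 integrated stress response genes were higher (median 0.44, adjusted p = 0.000115), 6 of them adjusted over the list alone, with SLC7A5 at 99.1 ± 16.9 CPM (SD, n = 5) against group means of 65.9 to 81.5 CPM. NF-kB and inflammatory genes were higher in 26 of 32 (median 0.45, adjusted p = 0.0164), 3 of them adjusted over the list alone, with CXCL8 at 39.4 ± 14.0 CPM against 24.5 to 29.7 CPM. Proliferation genes were lower in 27 of 40 (median -0.15, adjusted p = 0.00367), with KIF20A at 47.0 ± 8.28 CPM against 55.9 to 74.2 CPM, and acinar genes were higher in 19 of 19 (median 1.54, adjusted p = 0.00633). PPP1R15A at 46.1 ± 14.8 CPM against 18.6 to 28.5 CPM (adjusted p = 0.117) and CYP2S1 at 9.51 ± 3.56 CPM against 4.86 to 4.92 CPM (adjusted p = 0.14) had the smallest p after the gene named next and did not pass.

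edgeR called 1 gene in blood-activating against the rest, AL355075.4 (log2 fold change 6.17, SE 0.841, adjusted p = 0.0363), with 4253 at an unadjusted p under 0.05, and DESeq2 called 549 genes and limma voom 4988. AL355075.4, on chromosome 14 at 20343048 to 20343685, contains the whole of RPPH1 on the same strand, 333 bases. In CPM without TMM scaling it stood at 167.7 CPM in blood-activating 01 and 126.4 CPM in blood-activating 08, both RN7SK-high, and at 0.537 to 1.48 CPM in the other 18 libraries. Without the 5 RN7SK-high libraries its log2 fold change was 0.35 (adjusted p = 1), and the integrated stress response (adjusted p = 0.128) and NF-kB (0.203) calls ended. Leaving out blood-activating 04 gave 752 genes, heat-clearing 02 gave 9, heat-clearing 01, blood-activating 06 or blood-activating 09 gave 1, and the other 15 fits gave 0. Of the lists, NF-kB ended without spleen-strengthening 02 (0.0525) or blood-activating 01 (0.112) or 06 (0.0868), proliferation without blood-activating 08 (0.324) and acinar genes without blood-activating 06 (0.303).

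Heat-clearing against the other 3 treatments gave lower mitochondrially encoded mRNAs, in 12 of 13 members (median -0.33, adjusted p = 7.27e-09), with MT-ND4 at 22880 ± 3990 CPM (SD, n = 5) against group means of 25800 to 28250 CPM. This and the next list call had an adjusted p = 0.999 with an estimated correlation. The mean log2 CPM of the mitochondrial list was 12.27 and 12.56 in the RN7SK-high libraries heat-clearing 01 and 02. It was 13.03 to 13.24 in the other 3 heat-clearing libraries, within the range of 12.96 to 13.55 of the libraries of the other groups that are not RN7SK-high. Without the RN7SK-high libraries the mitochondrial call had an adjusted p = 0.00115 and the interferon call 0.000351. Type I interferon genes were lower in 30 of 38 (median -0.22, adjusted p = 0.000126), with OAS2 at 147.0 ± 12.8 CPM against 176.9 to 197.1 CPM. In both lists 0 members passed over all genes or adjusted over the list alone. TMUB2 at 14.4 ± 2.31 CPM against 8.69 to 12.2 CPM and the DNA break repair gene RAD50 at 63.5 ± 8.55 CPM against 73.1 to 81.5 CPM were among the single genes with the smallest p and did not pass (adjusted p = 0.992). edgeR called 0 genes with 1199 at an unadjusted p under 0.05, DESeq2 called 5 and limma voom 3.

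Yin-nourishing against the other 3 treatments gave higher proliferation genes, in 24 of 40 members (median 0.11, adjusted p = 0.013), 3 of them adjusted over the list alone, with KIF20A at 74.2 ± 9.16 CPM (SD, n = 5) against group means of 47.0 to 63.5 CPM and CCNB2 at 53.4 ± 7.64 CPM against 32.4 to 47.0 CPM. This and the next list call had an adjusted p = 0.883 with an estimated correlation. Mitochondrially encoded mRNAs were higher in 11 of 13 (median 0.21, adjusted p = 0.0032), with MT-CO2 at 35430 ± 3426 CPM against 22750 to 35080 CPM. The mitochondrial ribosomal protein gene MRPL32 at 22.1 ± 1.89 CPM lay above all 15 other samples, whose group means were 16.7 to 18.1 CPM. MARVELD3 at 3.75 ± 0.675 CPM lay below all 15, with group means of 6.39 to 7.44 CPM. Neither passed (adjusted p = 0.497 and 0.472). edgeR called 0 genes with 2263 at an unadjusted p under 0.05, DESeq2 called 48 and limma voom 0. The mitochondrial call ended without the RN7SK-high libraries (adjusted p = 0.353), and the proliferation call without yin-nourishing 05 (0.427) or blood-activating 08 (0.0607).

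Across all 4 treatments at once, genes with a small p included NAB2, PPP1R15A, CDK5R1 and CD320, the receptor that takes up vitamin B12, and PHACTR3, a regulator of protein phosphatase 1 and actin. CD320 was at 4.91 CPM in spleen-strengthening and 4.97 CPM in yin-nourishing samples against 9.53 CPM in heat-clearing and 10.6 CPM in blood-activating samples, and it too was higher in the RN7SK-high libraries of both of these groups. PHACTR3 was at 14.8 CPM in spleen-strengthening samples against 5.23 CPM in heat-clearing samples. None passed (adjusted p = 0.172 for all of these), and edgeR called 0 of 24790 genes, with 3824 at an unadjusted p under 0.05, while DESeq2 called 1259 and limma voom 2099. Leaving out heat-clearing 03 gave 378 genes, blood-activating 04 gave 10 and heat-clearing 01 gave 1, and leaving out the RN7SK-high libraries gave 1, APOL1 (adjusted p = 0.0185).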

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

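All tests in this part were chosen after the results they weigh were seen, except the random regroupings by the count of genes past adjustment and the test of a few genes taking most of the counts.

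A sample was singled out here when its gap to the nearest of the other 4 samples of its group took up more of the group's whole range than Dixon's test allows. This happened in 20 of 268 groups of 5 tested, where a rate of 1 in 20 would give 13.4. That rate holds for independent, normally distributed values. CPM are skewed and at times 0, and some of the measures share 1 signal, so 13.4 is not a fair reference. Yin-nourishing 10 accounts for 5 of these, heat-clearing 03 for 4, and blood-activating 06 and yin-nourishing 07 for 3 each. SH2D5 stood at 0.0374 CPM in spleen-strengthening 02 and at 0 in the other 4 (gap over range 1). Genes highest in 1 sample, with the value, the nearest other value and the gap over range, were PCK2 in blood-activating 01 (7.48, 4.34, 0.8), IL1B in yin-nourishing 04 (37, 23.3, 0.736), TRIM22 in spleen-strengthening 06 (44.5, 32.3, 0.76), CYP2S1 in heat-clearing 02 (6.51, 4.65, 0.876) and PHACTR3 in yin-nourishing 07 (10.7, 8.64, 0.787). Genes lowest in 1 sample were CEBPB in heat-clearing 03 (26.6, 41.3, 0.721), NFKB2 in yin-nourishing 07 (8.41, 10.5, 0.731), MSH6 in yin-nourishing 07 (56.1, 71.4, 0.78), MCM6 in yin-nourishing 10 (29.1, 39.8, 0.769) and IRF9 in yin-nourishing 10 (9.54, 74.4, 0.809).

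The other 9 are pancreatic acinar signals, each far above the rest of its group in heat-clearing 03, yin-nourishing 10 and blood-activating 06. For the trypsinogen gene PRSS1 the values were 19.8, 133 and 112 CPM (gap over range 0.927, 0.944 and 0.975), for colipase CLPS 6.52, 108 and 95.6 CPM (0.913, 0.952 and 0.96), and for the acinar list, summed in CPM without TMM scaling, 396, 1107 and 1016 CPM (0.817, 0.911 and 0.931). Treatment as the whole cause is argued against, since 2 treatments hold both a library above 100 CPM and 1 below 10 CPM. Carry-over of a small part of the highest library into the next is argued against as well, since the next library held nearly as much (ratio 1.09). A source common to both libraries was not tested, and this ratio says nothing about it. RNA of acinar cells is a candidate source: 19 of 19 list members reached 1 CPM or more in both of the highest libraries, and the members ranked alike in them (Spearman 0.991). In the 9 libraries with a sum below 10 CPM the insulin gene INS had 0 counts, and in the same 3 libraries it had 163, 68 and 95 counts, while the glucagon gene GCG had 16, 9 and 5 counts there and its most, 22, in yin-nourishing 07. Whether such RNA would be of the host or of the tumour, and human or mouse, stays open.

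The 5 RN7SK-high libraries stand apart from the other 15 in many genes. Treatment as the whole cause is argued against, since 2 treatments have libraries on both sides. Whether a few genes taking most of the counts are the cause was not decided. On the 15463 nuclear protein-coding genes alone, with their own totals, the share of distance between the 5 and the 15 libraries was 14.7%. On all 24790 tested genes it was 12%. The separation was thus present on nuclear protein-coding genes as well. Each gene counts alike in this distance and the counts were TMM-normalised, so leaving out a few abundant genes could hardly lower the share, whatever the cause. GC content bias may be part of the cause: within treatments the difference between the 2 kinds of library followed transcript GC content (Pearson r = 0.581 over 7112 genes). The host marker score was 1.101 ± 0.452 in the 5 and 0.302 ± 0.573 in the other 15 (mean ± SD), with overlapping ranges, and its part in the difference was not tested. A batch of preparation or sequencing is not labelled and was not tested, and a response of some tumours to 2 of the 4 treatments stays open.

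Between spleen-strengthening and blood-activating, the mitochondrially encoded list and the integrated stress response list answered differently to the RN7SK-high libraries. With a term for these libraries the mitochondrial median went from 0.29 to -0.06 (-0.062), so the RN7SK-high libraries are a candidate cause of that call. For the integrated stress response list the same term moved the median from -0.59 to -0.30 (-0.298, adjusted p = 0.000472), and leaving them out moved it to -0.21 (adjusted p = 0.00793). These p-values use the preset correlation, the call itself did not pass with an estimated correlation (adjusted p = 0.642) or in the exact test (adjusted p = 0.142), and only blood-activating 04 and 06 remain in the fit without the 5. Compared as 1 mean per library in a linear model, the difference was -0.64 (SE 0.13), -0.43 with the term (SE 0.12) and -0.47 without the libraries (SE 0.111). The list and pair were picked from these same data, and the SE makes no allowance for that. Differences of more than 3 SE are thus only weak evidence against the RN7SK-high libraries as the whole cause. Part of the size may come from them. In the other comparisons of blood-activating, with yin-nourishing, heat-clearing and the rest, the list's calls ended without these libraries. That fit also has fewer samples. With the GC slope as a covariate the median was -0.246 (adjusted p = 0.000667 with the preset correlation), and the list means were not compared with that covariate. The host marker score was built from the lists of fibroblasts, endothelium and macrophages. With it as a covariate the median was -0.50 (-0.497, adjusted p = 0.000422 with the preset correlation) and the difference of means -0.53 (SE 0.123). With the same limit, this argues against RNA of these cells as the whole cause. The acinar and keratinocyte lists were not part of the score, so RNA of such cells was not tested. Treatment stays open as a hypothesis for what remains.

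Random regroupings test whether chance can be excluded, with 100 splits for each comparison, the real one included. For a pair its 10 samples were regrouped, and otherwise all 20. For heat-clearing against spleen-strengthening, fewer than 5 of 100 splits, the limit set in advance, reached the count past adjustment (2 genes, 3 of 100, highest other 1168). It was the only comparison under this limit, and no allowance was made for the number of comparisons. The count at an unadjusted p under 0.05, a measure added later, was not rare (2844, 13 of 100, highest other 5088). Chance is therefore not firmly excluded for this pair. Chance cannot be excluded for spleen-strengthening against the rest (2 genes, 5 of 100, highest other 2731, and 3145 unadjusted, 3 of 100, highest other 6180) or blood-activating against the rest (1 gene, 14 of 100, highest other 3, and 4253 unadjusted, 2 of 100, highest other 4789).

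In the other 8 comparisons edgeR called 0 genes, a count that all 100 splits reach by construction, so the adjusted count says nothing about chance there. The unadjusted count was reached in fewer than 5 of 100 splits for 3 of them: spleen-strengthening against blood-activating (5087, 2 of 100, highest other 5299), yin-nourishing against blood-activating (4512, 2 of 100, highest other 4940) and the 4 groups at once (3824, 4 of 100, highest other 5082). It was reached more often for heat-clearing against yin-nourishing (2547, 11 of 100, highest other 4220), heat-clearing against blood-activating (460, 76 of 100, highest other 7378), spleen-strengthening against yin-nourishing (1169, 25 of 100, highest other 1651), heat-clearing against the rest (1199, 23 of 100, highest other 6922) and yin-nourishing against the rest (2263, 13 of 100, highest other 4583). This count does not exclude chance by itself, since it moves with where the RN7SK-high libraries fall. For the 4 groups at once its median was 513.5 over the 66 splits with at most 2 of these libraries in a group, 1659 over the 31 with 3, as in the real grouping, and 4482 over the 3 with 4. The 31 ranged from 698 to 3824, so the real grouping was the highest of them. They differ in where the rest of these libraries fall, so they are not all matched to the real grouping. Past adjustment the highest other splits of these 8 were 3992 for heat-clearing against the rest, 1 for yin-nourishing against the rest, 1137 for the 4 groups at once, 1 for heat-clearing against yin-nourishing, 5265 for heat-clearing against blood-activating, 3 for spleen-strengthening against yin-nourishing, 4 for spleen-strengthening against blood-activating and 2 for yin-nourishing against blood-activating. DESeq2 and limma voom counts stand with each comparison above. Splits that call many genes where the real split calls few point to a structure of the samples other than treatment, and the split with 5265 puts all 5 RN7SK-high libraries into 1 group.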

How the results depend on the processing

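The fit without the 5 RN7SK-high libraries, the term for them and the GC slope covariate were chosen after the results were seen, and the other alternatives were planned.

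Counts of genes moved most with the tool. DESeq2 called 67 genes for heat-clearing against spleen-strengthening, 32 for heat-clearing against yin-nourishing, 9 for heat-clearing against blood-activating, 33 for spleen-strengthening against yin-nourishing, 1933 for spleen-strengthening against blood-activating and 1055 for yin-nourishing against blood-activating. Against the other 3 it called 5 (heat-clearing), 139 (spleen-strengthening), 48 (yin-nourishing) and 549 (blood-activating), and among all 4 treatments 1259. limma voom called 1, 4910 and 4172 for the last 3 of these pairs, 3, 5 and 4988 for heat-clearing, spleen-strengthening and blood-activating against the rest, and 2099 among all 4. The cause was not tested.

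The 2 genes of heat-clearing against spleen-strengthening became 0 with RLE or upper-quartile normalisation, no filter, the host marker score, the RN7SK-high term, the GC slope, without the 5 RN7SK-high libraries and with only the 10 samples of the pair, and 1 with the strict filter, the title letter and a minimum absolute log2 fold change of 1. SH2D5 is not tested under the strict filter. The 2 genes of spleen-strengthening against the rest became 0 with upper-quartile normalisation, the replicate block, the host marker score, the RN7SK-high term, the GC slope and without the 5 libraries, and 1 with the strict filter and the minimum fold change. The 1 gene of blood-activating against the rest became 0 with the title letter, the host marker score, the RN7SK-high term and the GC slope, and 2 with no filter or the replicate block. With the replicate block NAB2, SH2D5 and AL355075.4 no longer passed in any comparison where they had passed. Any genes counted in those comparisons with the block are therefore other genes. Spleen-strengthening against blood-activating gave 2 with no filter, the replicate block or the pair alone and 3 without the 5 libraries. The replicate block gave 1 gene for heat-clearing against blood-activating, for yin-nourishing against blood-activating and among all 4 treatments, the GC slope 1 for heat-clearing against blood-activating, and leaving out the 5 libraries 1 among all 4. Apart from SH2D5 under the strict filter, the cause was not tested. The replicate numbers gave little sign of pairing: of 12 pairs with the same number 1 correlated above 0.1. That pair, heat-clearing 01 and blood-activating 01 (0.17), is of RN7SK-high libraries. Pairing is not excluded, since pairs of RN7SK-high libraries with different numbers also reached only 0.096 to 0.154.

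Leaving out 1 library at a time gave 0 to 2 genes for heat-clearing against spleen-strengthening, 0 to 1 for spleen-strengthening against yin-nourishing, 0 to 2002 for spleen-strengthening against blood-activating and 0 to 361 for yin-nourishing against blood-activating. It gave 0 to 3 for spleen-strengthening against the rest, 0 to 752 for blood-activating against the rest and 0 to 378 among all 4. The highest values came without blood-activating 04 for 2002, 361 and 752, and without heat-clearing 03 for 378. Neither library is RN7SK-high, so leaving it out raises the share of RN7SK-high libraries in its group. Leaving out blood-activating 06, which is not RN7SK-high either, raised none of these counts. The cause of the high values was not tested. In the other 4 comparisons all 20 such fits by edgeR gave 0, as did the fit of all samples (its counts at an unadjusted p stand in the report). The share of distance between treatments was 19.65 to 21.55% over these fits, and 21.75% without the 5 libraries, where it no longer passed and lay close to the mean of 21.43% under permuted labels.

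Among the 241 results for single named genes, those past the threshold in the main fit kept their direction in every alternative run. For heat-clearing against spleen-strengthening the log2 fold change was 0.84 to 0.98 for NAB2 and 5.56 to 8.89 for SH2D5. For spleen-strengthening against the rest it was -0.85 to -0.72 for NAB2 and -8.73 to -5.57 for SH2D5. For AL355075.4 in blood-activating against the rest it was 0.35 to 6.5. Whether named genes that did not pass changed direction is not given. The 45 list calls numbered 76 with the GC slope, 0 with an estimated correlation and 6 with fry, 39 to 65 under the other alternatives that keep or leave out the same libraries throughout, and 31 (without spleen-strengthening 07) to 66 (without spleen-strengthening 05) leaving out 1 library at a time. Of the 45, those that still passed in the same direction were 45 with RLE, 45 with the title letter, 44 with no filter, 41 with upper-quartile normalisation, 41 with the strict filter, 38 with the host marker score, 36 with the RN7SK-high term, 33 with the GC slope, 27 without the 5 libraries, 25 with the replicate block and 4 with fry. Leaving out 1 library ended 88 of 900. The mitochondrially encoded list changed direction in spleen-strengthening against blood-activating (adjusted p = 0.769 with the RN7SK-high term, 0.0544 with the GC slope), in yin-nourishing against blood-activating (0.649 and 0.314) and in spleen-strengthening against the rest (0.843 with the GC slope). The cause was not tested beyond these terms. What depth limits was not tested, and the smallest library held 81.7 M counts.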

Other observations

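The exact tests of list means in this part were chosen after the list results were seen.

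Of the 41 lists tested, 14 passed the camera test in at least 1 of 10 contrasts and 27 in none. The smallest adjusted p of these 27 over the 10 contrasts was 0.0509 for mucins and for angiogenic factors, 0.0613 for xenobiotic metabolism, 0.0673 for histones, 0.0677 for heat shock genes, 0.0929 for antigen presentation, 0.116 for macrophages, 0.145 for ferroptosis genes, 0.164 for TGF-beta targets, 0.179 for the unfolded protein response, 0.179 for host fibroblasts, 0.18 for the classical tumour subtype and 0.195 for NRF2 targets. It was 0.216 for skeletal muscle, 0.242 for epithelial genes, 0.305 for adipocytes, 0.322 for apoptosis, 0.415 for small structural RNA, 0.438 for metallothioneins, 0.444 for autophagy, 0.457 for fatty acid genes, 0.471 for MYC targets, 0.529 for mesenchymal genes, 0.537 for lymphocytes, 0.684 for endothelium, 0.709 for cholesterol genes and 0.8 for p53 targets. Over the 20 libraries the mean log2 CPM was 6.73 for the basal-like and 2.13 for the classical tumour subtype list, 1.5 for host fibroblasts, 0.14 for endothelium, -0.33 for lymphocytes, -0.48 for macrophages, -1.17 for skeletal muscle and -1.25 for adipocytes.

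By exact permutation of the mean level of each list per library, 0 lists of 41 passed after adjustment in any of the 10 contrasts. For the 6 pairs this result says little, since 5 against 5 samples give no exact p below 0.00794, which passes over 41 lists only where several lists reach it together. The number at an unadjusted exact p under 0.05 was 12 for spleen-strengthening against blood-activating, 6 for yin-nourishing against blood-activating, 5 for heat-clearing against spleen-strengthening, 2 for heat-clearing against yin-nourishing, 2 for spleen-strengthening against yin-nourishing and 1 for heat-clearing against blood-activating. Against the rest it was 10 for spleen-strengthening, 8 for blood-activating, 2 for yin-nourishing and 1 for heat-clearing. The smallest adjusted p was 0.0661, for angiogenic factors in spleen-strengthening against the rest (mean log2 CPM 3.62 ± 0.21 against 4.03 ± 0.22, SD, n = 5 and 15, exact p = 0.00161). For the integrated stress response list the means were 2.97 ± 0.14 in spleen-strengthening and 3.61 ± 0.29 in blood-activating samples (SD, n = 5, exact p = 0.00794, adjusted p = 0.142).

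IRF9 lies over its whole span, 5513 bases, within AL136295.5 on the same strand, and the counts of the 2 genes trade places between libraries. Yin-nourishing 10 held 9.54 CPM of IRF9 and 93.7 CPM of AL136295.5, and yin-nourishing 05 held 74.4 and 1.09 CPM. The sums of both were 82.1 ± 20.9 CPM in heat-clearing, 96 ± 16.2 CPM in spleen-strengthening, 96.2 ± 13.9 CPM in yin-nourishing and 69.3 ± 16.5 CPM in blood-activating samples (SD, n = 5). Of the 60 genes followed by name, 34 share part of their span with another annotated gene, 24 of them with 1 on the other strand.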
